A study of Culex quinquefasciatus with 10 samples.

How the data were processed

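Gene expression was measured in larvae of Culex quinquefasciatus, day 2 of instar 4, of the strains JPal-per and Ogasawara, on 10 custom Agilent 2-colour arrays. Per the labels, larvae were fed ground insect pellets, and total RNA was amplified linearly into cRNA that took up Cy3 or Cy5 CTP. Per the labels, arrays with the same replicate number carry the same 2 extracts with the dyes exchanged, so they were counted as 1 replicate, giving 5 replicates of the strain ratio. Each array holds 10807 spots, of which 10263 are not controls, 465 are positive controls and 79 are negative controls, and each probe has up to 4 spots.

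Per the file headers, the deposited scanner files come from Agilent Feature Extraction 8.1.1.1 (replicate 1), 9.5.3.1 (first arrays of replicates 2 to 5) and 10.5.1.1 (second arrays of replicates 2 to 5), and hold spot signals in intensity units. The same files give background medians and processed signals, also deposited as intensity, and 0 or 1 marks for saturation, outliers and signals well above background. The deposited value table holds the authors' log10 ratio, which equals the dye-normalised log ratio of the scanner software turned to JPal-per over Ogasawara on every array. The mean and background signals were used for the fit, and the processed signals and the value table as alternatives. The software's multiplier for a signal well above background was 2.6 on the arrays of replicate 1 and 13 on the others, so more probes count as above background on the former. The slides were scanned at 10, 5 or 2 µm in 3 scan batches. The arrays of replicate 1 share a slide, replicates 2 and 3 share slides, and replicates 4 and 5 share slides.

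Spot signals were background corrected with normexp and an offset of 50, and loess was fitted within each array with control spots and outlier spots at weight 0. The log2 ratios were turned to JPal-per over Ogasawara, averaged over the spots of a probe, and averaged over the 2 arrays of a replicate. Probes were tested if at least 0.5 of their spots were well above background in at least 1 channel on at least 5 of the 10 arrays, which left 1488 of 2568 probes. The 5 replicate ratios were fitted with limma 3.58.1 (intercept alone, eBayes, two-sided) in R 4.3.3 with statmod 1.5.0, and p-values were adjusted by Benjamini-Hochberg over all tested probes, with a threshold of 0.05. SD is that of the 5 replicate ratios. The dye effect was fitted in the same way on the part of the ratio that changes sign between both orientations. Each sequence was represented by its tested probe with the highest mean log2 signal. In 45 of the 59 sequences past the threshold with at least 5 tested probes, that probe had a larger ratio in size than the median probe (median gap 0.12).

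The array names its sequences by class codes or accessions, without descriptions, and no genome was at hand. The locus tags and accessions of the annotation table did not match any name on the array. The description patterns planned for the gene lists were therefore replaced by array codes once these were seen: 8 of the 26 planned lists had members and 18 had none, and 5 further lists were added after the files were seen (actin, ESTA, ESTB, the AY388 run and the other accession-named sequences). What a code stands for was read from the code and, in some classes, checked against conserved peptide segments in the translated probes. Probes were compared base by base over their length, and by BLAST+ 2.17.0. Lists with at least 5 tested sequences were tested with limma camera (preset correlation 0.01), with an estimated correlation and with fry beside it, adjusted over 10 lists. The sequences named in the text were chosen by a rule written before the data were examined. Among sequences past the threshold with the same sign in all 5 replicates, it took the 15 with the highest and the 10 with the lowest ratios. It added P450, glutathione transferase and esterase members with at least 2-fold, at most 10 of each, and the 3 largest past the threshold of each other list. That last part was also applied to the lists added after the files were seen. AY388560_100, AY388568_108, ESTA_001 and ESTA_003 were named through those lists alone, so they were not fixed beforehand. The rule named 36 sequences. Other sequences that appear in the text were chosen after their values were seen.

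Alternatives changed the background correction, the normalisation (median centring, processed signals, the authors' value table), the filter, the orientation, the batch, the replicate block, the test and the probe that stands for a sequence, and left out each replicate in turn. The pairing of the arrays of replicates 4 and 5 the other way, and a fit without both replicates, were added after the data were seen. The fit was tested on simulated data with 200 of 1488 probes changed: 65.7% of changes of 0.5 log2 units and 98.5% of changes of 1 log2 unit were recovered, with 13 false calls among 188. The simulated replicates and probes were independent, while here replicates share slides and probes share sequences, so these rates may not hold for the data. The array means limit the precision through the number of arrays, and signal over background through the dim probes. Figures were drawn with matplotlib 3.10.9.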

Results

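Whole larvae of the mosquito Culex quinquefasciatus were compared between JPal-per, a strain the labels call insecticide resistant, and Ogasawara, a strain they call susceptible. Larvae were taken on day 2 of instar 4, and total RNA of both strains was hybridised together on 10 custom arrays of 60-base probes. The arrays formed 5 biological replicates, and by the numbers in the labels each replicate was hybridised on 2 arrays with the dyes exchanged, so the replicate was the unit of comparison (n = 5). The array held 2568 probes for 228 sequences, most of them named by class codes such as P450, ESTA, ESTB or GSTF followed by a number. The median signal over background ranged from 2.65 to 4.04 in Cy3 and from 1.25 to 3.06 in Cy5. The number of probes well above background in either channel ranged from 1330 to 2316 per array. The number of arrays limits the precision of every value below.

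The strain comparison asked which sequences differ in level between larvae of the resistant and the susceptible strain. Resistance went with the strain on every array, so it cannot be told apart from other differences between these strains. Sequence differences under the probes, which can also change a ratio, were looked at for P450_032 and P450_031 alone. JPal-per larvae carried far more of the P450-coded sequence P450_032 (23.9-fold), and esterase-coded sequences were higher by up to 2.59-fold (ESTB_001). Ogasawara larvae carried far more of AF222024 (27.9-fold), a sequence with conserved segments of the alpha-amylase family, which includes maltases that digest sugars, and of P450_031 (11.5-fold). Of 1488 probes tested, 810 (54.4%) passed an adjusted p of 0.05, with 462 higher and 348 lower in JPal-per. On the brightest probe of each of 168 tested sequences, 42 were higher, 39 were lower and 87 did not pass. In 11 sequences some probes were called higher and others lower, so that probe does not stand for all; M91082_003, for example, was higher at 0.22 on its brightest probe but had 35 probes called lower and 2 called higher, with a median of -0.23.

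Outside the enzyme lists, the accession-named sequences held some of the largest ratios. AF222024 had a log2 ratio of -4.80 ± 0.47 (SD, n = 5, adjusted p = 1.26e-04), and all 29 of its tested probes were below 0, from -4.80 to -0.30, with a median of -2.30. The ratio of AF222024_014 was -5.85 with a normexp offset of 0, -6.24 from the processed signals and -2.40 with the mean of its probes. AF202953_013, which carries an iron-sulphur segment typical of aldehyde oxidases and xanthine dehydrogenases, was higher by a log2 ratio of 1.28 ± 0.28 (SD, n = 5, adjusted p = 5.6e-04). That value comes from the brightest of 85 probes, whose median ratio was 0.26. AF468495_025 stood at 1.88 ± 0.43 (SD, n = 5) on its brightest probe, with a median of 0.30 over 14 probes, and at 2.78 from the processed signals. The Ogasawara signal of that probe was well above background on 8 of the 10 arrays. AY388563_103 was higher by 1.07 ± 0.16 (SD, n = 5), and its 4 tested probes all passed. AY388560_100 was lower, at -0.93 ± 0.25 (SD, n = 5), with all 16 tested probes past the threshold. AY388568_108 was lower as well, at -0.76 ± 0.34 (SD, n = 5), and its 3 tested probes had a median of -0.30; its call ended without replicates 4 and 5. The calls of AY388560_100 and AY388568_108 ended with each array centred on its median in place of loess (adjusted p = 0.0599 and adjusted p = 0.0819).

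**Figure D1:**
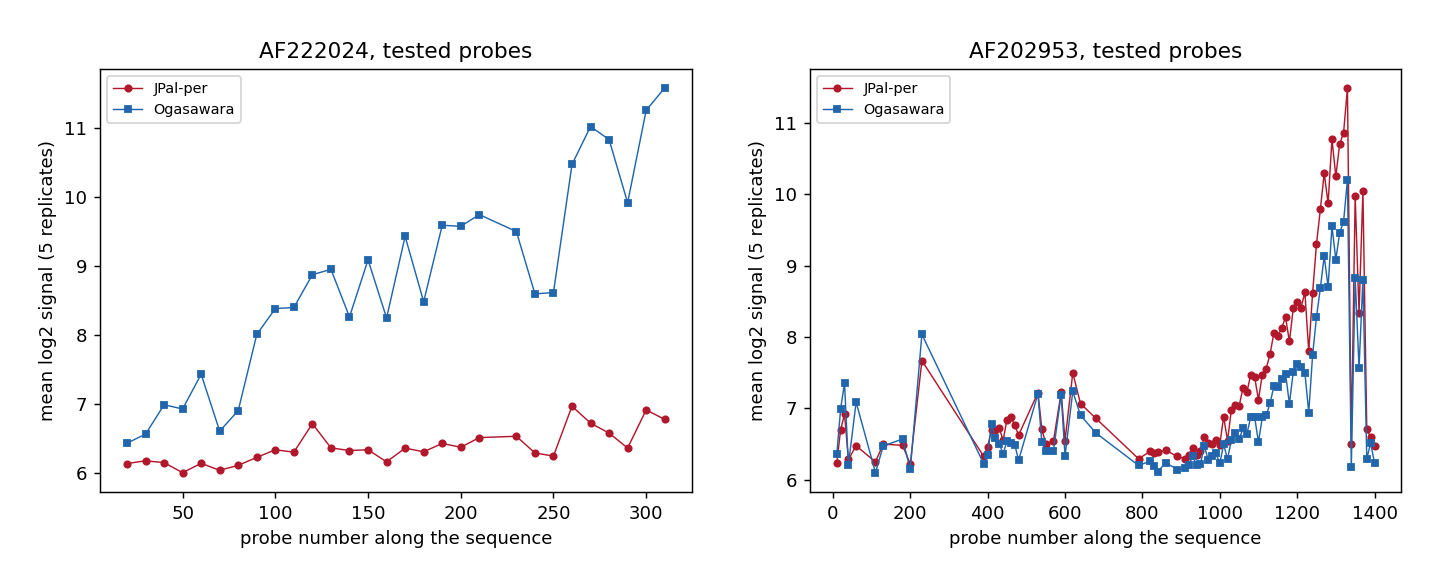
Mean log2 signal of the JPal-per and Ogasawara extracts over 5 replicates (vertical axis, brightness) by probe number along AF222024 and AF202953 (horizontal axis, serial number). Over the 29 probes of AF222024 the JPal-per signal stayed between 6.01 and 6.97 while the Ogasawara signal ranged from 6.43 to 11.6; AF202953 had its highest signal and ratio, 1.28, at probe 1330.

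The count of 810 was the same in a fit of separate channels with the replicate block, as that fit repeats the main test. The count was 574 with the replicate batch as a random block. It was 741 with the arrays of replicates 4 and 5 paired the other way, 362 within the batch of replicates 2 and 3 and 723 within that of replicates 4 and 5, the batch of replicate 1 holding a single replicate, and it fell to 363 with median centring, 514 without replicate 4 and 499 without replicate 5. Without replicates 4 and 5 it was 141, and the excess of higher probes turned (66 higher, 75 lower). With the replicate batch as a random block, the correlation between replicates of a batch was estimated at 0.599. The main fit takes the replicate ratios as independent, so its adjusted p-values may be too low.

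Differences of at least 2-fold were asked for separately, since small ratios can pass with a small spread. P450_032, P450_004, P450_014, P450_061, P450_054 and P450_058 made up 6 of the 14 sequences at least 2-fold higher in JPal-per, and all 5 ESTB sequences were among the others. P450_031, P450_033, P450_030, P450_034 and P450_037 made up 5 of the 6 sequences at least 2-fold lower, with AF222024 as the other. Membership rests on the brightest probe: with the mean of a gene's probes P450_061, P450_058, P450_034, P450_037, AF468495_025, AF202953_013 and all 5 ESTB sequences were below 2-fold. Counted over probes, 147 passed with at least 2-fold, 78 higher and 69 lower. The excess of higher probes turned with a normexp offset of 0 (102 higher, 131 lower), without replicates 4 and 5 (41 and 48), without replicate 1 (69 and 75), within the batch of replicates 2 and 3 (61 and 82) and with only JPal-per in Cy5 (75 and 77). The split was 121 and 47 with median centring and 234 and 158 from the processed signals.

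The cytochrome P450 list asked whether these oxidases, which include enzymes that metabolise pyrethroid insecticides, differ between the strains. P450_032 had the highest ratio of all tested sequences, with a log2 ratio of 4.58 ± 0.42 (SD, n = 5, adjusted p = 1.26e-04), and its 5 probes ranged from 3.48 to 4.58. From the processed signals it was 5.42. The Ogasawara signal of P450_032 was well above background on 9 of the 10 arrays. Over the alternatives that gave a value, its ratio ranged from 4.12 to 5.42. P450_031 was lower, at -3.52 ± 0.81 (SD, n = 5, adjusted p = 5.1e-04), with its 5 probes between -3.52 and -3.14. P450_054 was 2.56-fold higher (log2 ratio 1.36 ± 0.12, SD, n = 5), on a probe that was saturated on 1 array in JPal-per.

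Of 69 tested members of the P450 list, 14 were higher, 21 were lower and 34 did not pass; the counts adjusted over the list alone were also 14 and 21. With median centring 15 members passed, 10 higher and 5 lower, so the excess of lower members turned. Among the higher members, P450_004 reached 4.07-fold (log2 ratio 2.02 ± 0.30, SD, n = 5) and P450_014 reached 3.90-fold (1.96 ± 0.80, SD, n = 5). From the processed signals P450_014 stood at 2.77, and with the mean of its probes P450_004 stood at 1.33. The Ogasawara signal of P450_014 was well above background on 9 of the 10 arrays. P450_061 reached 2.85-fold on its brightest probe (1.51 ± 0.55, SD, n = 5), with a median of 0.64 over 31 probes. P450_058 stood at 1.02 ± 0.35 (SD, n = 5), but its 10 probes went both ways, from -1.22 to 1.02. With the mean of a gene's probes in place of the brightest, P450_058 no longer passed (0.27, adjusted p = 0.091). Among the lower members, P450_033 fell to -1.36 ± 0.18 (SD, n = 5), and P450_030 to -1.34 ± 0.63 (SD, n = 5). P450_034 stood at -1.15 ± 0.22 (SD, n = 5) with a median of -0.38 over its probes, and P450_037 at -1.04 ± 0.49 (SD, n = 5). P450_036 and P450_015 lay at -0.95 each, with SD 0.56 and 0.13. In replicate 1 the ratios of P450_030, P450_037 and P450_036 were -0.26, -0.24 and -0.01, nearer to 0 than in the other replicates. The calls of P450_015, P450_036 and P450_037 ended with median centring. Without replicates 4 and 5 those of P450_014, P450_061, P450_058, P450_030, P450_036 and P450_037 ended. Their direction could not turn there, as they were chosen for the same sign in all 5 replicates.

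**Figure D2:**
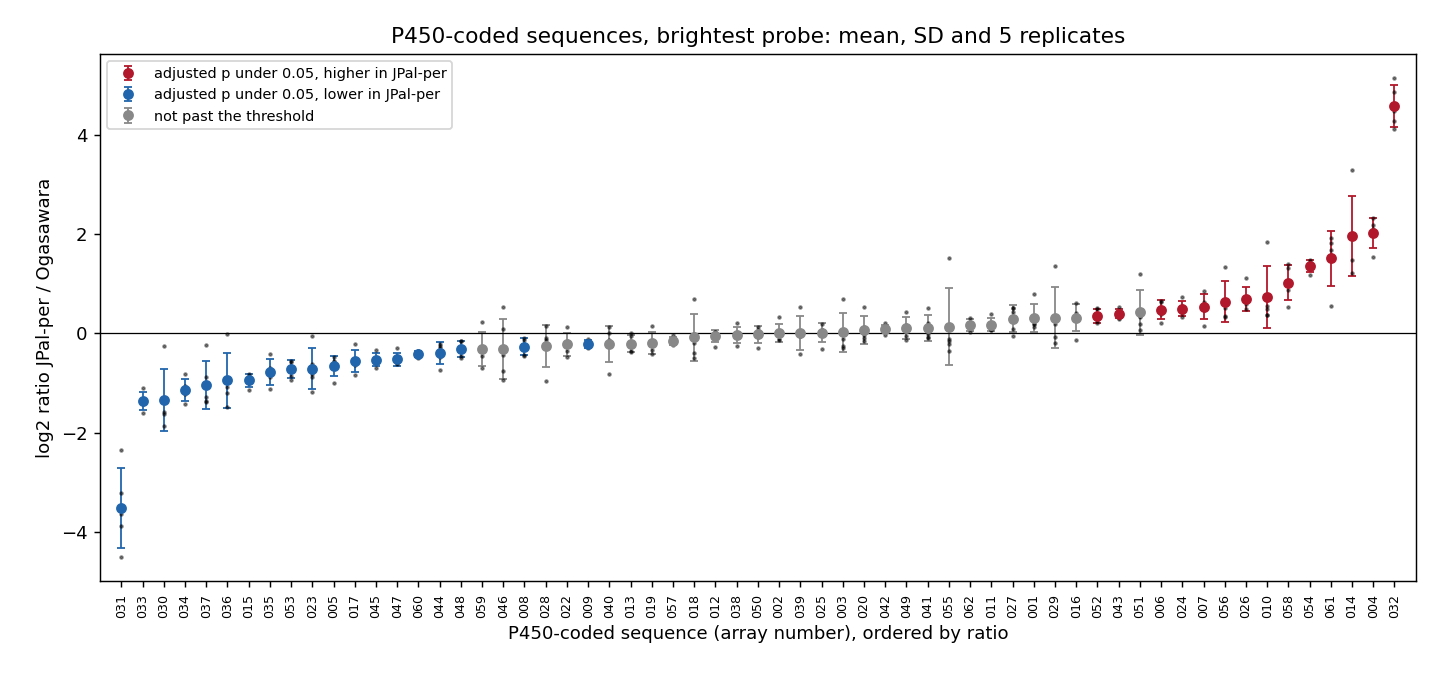
Log2 ratio of JPal-per over Ogasawara (vertical axis) for the P450-coded sequences on their brightest probe, ordered by ratio (horizontal axis); large points are means of 5 replicates, bars are SD and small points are the replicates. P450_032 sits highest at 4.58 and P450_031 lowest at -3.52; with median centring the list had 10 higher and 5 lower members past the threshold.

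As a set the P450 list did not shift one way, with camera adjusted p = 0.494 (direction down), a median log2 ratio of -0.04 and a mean of 0.0011. The mixed test of fry, which asks for change in either direction, gave adjusted p = 1.0e-05. That test does not set the P450 list apart. Every other tested list but the glutathione transferases (fry mixed adjusted p = 0.817) was under 0.05 as well, such as the insecticide target sites (5.3e-04) and the other accession-named sequences (8.0e-07). The codes A304 to A307 and A315, whose sequences all carry the heme-binding segment of P450s, had 0 higher, 2 lower and 4 not past the threshold of 6 tested, and 1 lower when adjusted over the list alone. The members past the threshold were A304_015 at -0.26 and A305_017 at -0.24, and both calls ended with median centring, within either batch of replicates, and without replicate 2 or replicate 4 (A305_017 also without replicate 3 or replicate 5). Both tested members of the codes A325 and A4AA, of 14 on the array, did not pass by the limma test, and 0 had an unadjusted p under 0.05. Neither CYP9M10 nor CYP4H34 is named on the array, so no value can be given for either. The P450 count was 23 within the batch of replicates 2 and 3, 32 within that of replicates 4 and 5 and 9 without replicates 4 and 5.

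The other gene lists asked whether further detoxification enzymes, their partners and insecticide targets differ. Esterases, which hydrolyse or bind ester insecticides, were higher in JPal-per almost throughout. Of 15 tested sequences coded ESTA, ESTB or ACHE, 14 were higher and 1 did not pass, and the count adjusted over the list alone was also 14. Camera gave adjusted p = 3.3e-05 for the list and adjusted p = 0.58 with an estimated correlation, and fry gave adjusted p = 0.00992. All 5 ESTB sequences were at least 2-fold higher, from 1.18 for ESTB_004 to 1.37 ± 0.38 (SD, n = 5) for ESTB_001, on their brightest probes. With the mean of their probes they lay from 0.69 (ESTB_004) to 0.83 (ESTB_001), and the median over the 109 ESTB probes was 0.73. All 8 ESTA sequences passed with lower ratios, up to 0.92 ± 0.49 (SD, n = 5) for ESTA_002, with ESTA_001 at 0.85 and ESTA_003 at 0.81. ESTA_001, ESTA_002 and ESTA_003 did not pass within the batch of replicates 2 and 3 (0.41, 0.47 and 0.37), and with median centring the calls of ESTA_001 and ESTA_003 ended. All 3 also lost their calls without replicates 4 and 5, where the median over the ESTA sequences was 0.65 against 0.72 in the main fit. The list is not made of independent genes, since all 109 tested ESTB probes and 111 of the ESTA probes share at least 50 of 60 bases with a probe of another sequence. Taken alone after these values were seen, ESTA gave camera adjusted p = 0.00462, and adjusted p = 0.655 with an estimated correlation. ESTB gave adjusted p = 0.00231, and adjusted p = 0.58 with an estimated correlation.

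Of 8 tested P450 redox partners, which pass electrons to P450s, 0 were higher, 5 were lower and 3 did not pass, and 5 were lower when adjusted over the list alone. The list median was -0.45, and camera gave adjusted p = 0.0317 and adjusted p = 0.58 with an estimated correlation, while fry gave adjusted p = 6.8e-05. The adrenodoxin-coded ADDX_006 and ADDX_005 lay at -0.98 ± 0.24 and -0.74 ± 0.29 (SD, n = 5), the cytochrome b5-coded CYB5_003 at -0.95 ± 0.10 (SD, n = 5), and the P450 reductase-coded NDRD_001 at -0.58 ± 0.26 (SD, n = 5). The remaining lower member was CYB5_004, at -0.33 on its 1 tested probe. The 5 lower members are not all independent. ADDX_005 and ADDX_006 were each tested on 1 probe, and these probes share 52 bases. CYB5_003 and CYB5_004 have 1 probe each that shares at least 50 bases with the other sequence. The camera call of the list also ended with a normexp offset of 0 (median -0.76, adjusted p = 0.0814) and within the batch of replicates 4 and 5 (median -0.41, adjusted p = 0.0502). It ended as well with only the arrays with Ogasawara in Cy5 (median -0.29, adjusted p = 0.272). With median centring the calls of CYB5_003 and ADDX_005 ended. That of ADDX_005 also ended without replicates 4 and 5, with its ratios at -1.23, -0.71 and -0.54 in replicates 1 to 3.

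None of 5 tested glutathione transferase sequences passed, with ratios from -0.07 to 0.08, and 0 had an unadjusted p under 0.05 by the limma test. On single probes of these sequences, 8 of 48 were higher and 1 was lower. Of the 8, 6 belong to GSTF_004, whose 9 probes had a median of 0.44 and a highest ratio of 0.76, while its brightest probe lay at -0.01. Of 5 tested insecticide target sequences, which code for sodium channels, acetylcholinesterases and acetylcholine receptors, 1 was higher and 4 did not pass. The member past the threshold was the acetylcholinesterase-coded ACHE_002 at 0.17 ± 0.07 (SD, n = 5). Its Ogasawara signal was above background on 5 of the 10 arrays, and from the processed signals its ratio was 1.01. With the p-values adjusted over the list alone 0 passed. The call of ACHE_002 ended with median centring, in each separate orientation of the dyes, within each batch of replicates, and without any one of replicates 2, 3, 4 or 5. Ribosomal protein S3 sequences had 3 of 4 members lower, RPS3_001 at -0.22, RPS3_004 at -0.18 and RPS3_003 at -0.16, but their direction turned with median centring and on the arrays with Ogasawara in Cy5. Those 3 calls also ended without any one of replicates 2, 3, 4 or 5. The same 3 members passed when adjusted over the list alone. Neither of the 2 actin sequences passed, at -0.13 and -0.12; this list was chosen after the files were seen. The run of 55 consecutively numbered AY388 sequences had 3 higher, 3 lower and 16 not past the threshold of 22 tested, and also 3 and 3 when adjusted over the list alone. The other accession-named sequences had 11 higher, 7 lower and 21 not past the threshold of 39 tested, and 8 higher and 6 lower when adjusted over the list alone. Both lists were chosen after the files were seen. Of the 10 lists large enough for the set test, 4 passed, 3 up and 1 down, and the 3 up were the esterase list and its parts ESTA and ESTB. With an estimated correlation 0 of the 10 lists passed, the lowest at adjusted p = 0.58.

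**Figure D3:**
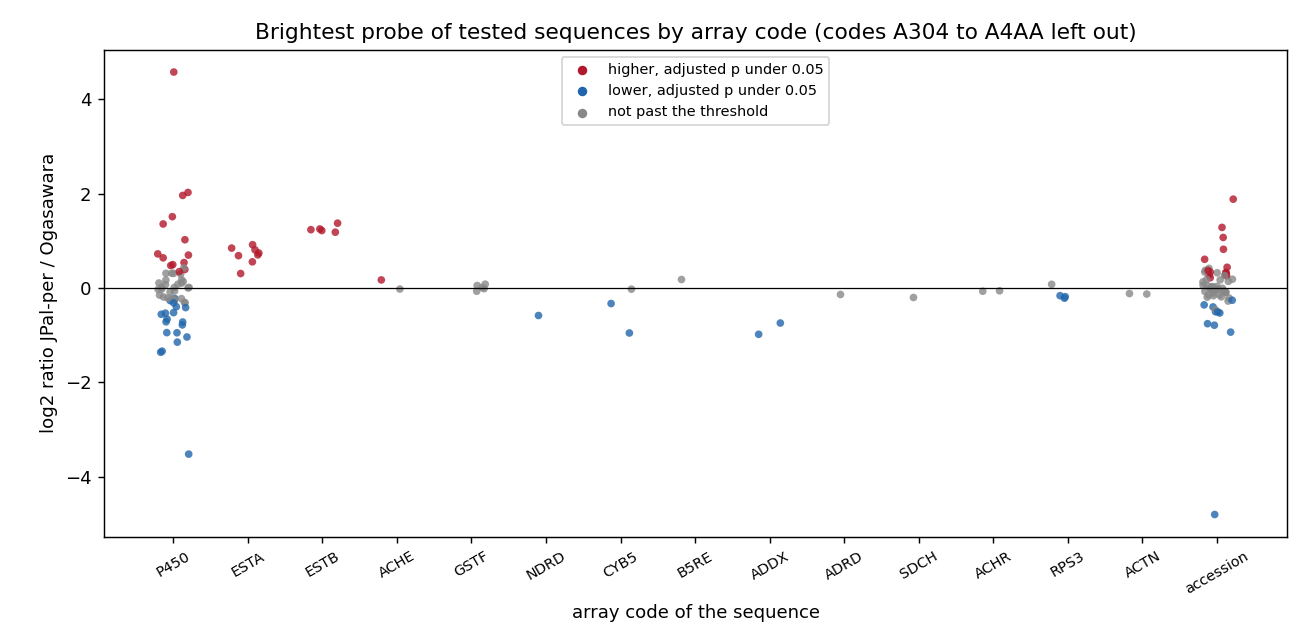
Log2 ratio of JPal-per over Ogasawara (vertical axis) on the brightest probe of tested sequences, grouped by array code (horizontal axis, codes A304 to A4AA left out); points are means of 5 replicates and colours give the result of the limma test. The ESTB sequences lie between 1.18 and 1.37 and the ESTA sequences between 0.31 and 0.92, while the tested GSTF sequences stay between -0.07 and 0.08.

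The dye comparison asked how far both orientations of the same extracts differ. Of 1488 probes, 12 passed the threshold for a dye effect, 5 higher and 7 lower in Cy5, and 0 of them reached 2-fold by the limma test; 474 had an unadjusted p under 0.05. The median size of the dye effect was 0.09 on the log2 scale, against 0.31 for the strain ratio. For replicates 2 to 5 the orientation also went with the scanner software version and the scan batch, so the dye cannot be told apart from these. The count was 258 with a normexp offset of 0 and 631 with median centring, and it ranged from 0 to 228 as each replicate was left out.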

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

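The tests of P450_032 and P450_031, the count of bright JPal-per probes of AF222024 and both tests of P450_058 were chosen after the results were seen; the offset test of AF222024 and the sign patterns were not. In 8 of 44 groups of 5 values, 1 value stood apart from the other 4, where chance gives about 1 in 20 groups. The groups pooled the ratios of the 36 named sequences with array measures. Among the ratios only ADDX_005, CYB5_003 and P450_061 were flagged, so the excess came mostly from array measures, all of replicate 1. Those measures are not independent, and the multiplier of replicate 1 set its counts above background apart beforehand. The log2 ratio of ADDX_005 was -1.23 in replicate 1 and between -0.71 and -0.52 in the others. That of CYB5_003 was -1.13 in replicate 2 and between -0.94 and -0.86 in the others. That of P450_061 was 0.55 in replicate 1 and between 1.58 and 1.92 in the others. Among the arrays with JPal-per in Cy5, the array of replicate 1 had a Cy3 signal over background of 2.75, against 3.87 to 4.04, and 2316 probes above background in either channel, against 1330 to 1518. Among the arrays with Ogasawara in Cy5, that of replicate 1 had a Cy5 signal over background of 2.78, against 1.25 to 1.52. It had 2229 probes above background, against 1377 to 1554, and 481 outlier spots, against at most 354. The arrays of replicate 1 were scanned in a batch of their own with a lower multiplier for signals above background.

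P450_032 and P450_031 had ratios of 4.58 and -3.52, the furthest apart of all P450 sequences. Cross-hybridisation was judged first by shared bases, and the most shared with another sequence was 42 of 60, over the bound of 40 set for excluding it, which decided nothing. Of 444 probes of other P450 sequences, 0 had a ratio as large in size as the smallest of the 10 probes (range -1.59 to 2.76). As the 2 sequences were picked for their extreme ratios, that outcome was largely set by the choice. Cross-hybridisation therefore stays open. Outside that code 9 probes were as large, all of AF222024, lower in JPal-per and with at most 24 bases shared with P450_031. A sequence difference under single probes was argued against by the smallest ratio of the 10 probes, 3.14 in size, and the dye or scan batch by the smallest ratio of either brightest probe on any of the 10 arrays, 2.22 in its own direction. Strain differences in transcript level, a transcript not probed here or a difference over the whole probed stretch may each remain, untested.

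AF222024 had ratios from -4.80 to -0.30 over its 29 probes, with a Spearman correlation of -0.93 between ratio and probe number across the probes, which are not independent replicates. The JPal-per signal stayed between 6.01 and 6.97 over these probes while the Ogasawara signal ranged from 6.43 to 11.6. The ratios thus differed mostly through the Ogasawara signal. A JPal-per signal near the background on every probe was argued against, since 6 of the 29 probes, the one at -4.80 among them, were well above background on all 10 arrays in JPal-per. The offset added to dim signals was argued against as the reason for the whole range, since with an offset of 0 the range was 1.11 times that with the offset of 50. The ratio nearest to 0 was -0.83 with an offset of 0, against -0.30. The offset may thus account for a part of the weakest ratios. For the other 23 probes a JPal-per signal near the background stays open. No biological explanation beyond the strain itself was tested.

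P450_058 had probes from -1.22 to 1.02, while P450_004 was higher on all 8 probes. Cross-hybridisation with P450_004 stays open: the 7 probes with at least 50 shared bases had a mean ratio 0.21 above that of the other 3, with an exact permutation p = 0.7. The 5 probes that share at least 57 bases lay between 0.60 and 1.02 and the others between -1.22 and 0.51, a limit picked after these values were seen and not tested. Dim probes as the reason were argued against, as 3 probes with a negative ratio were well above background on all 10 arrays in both strains. No biological explanation was tested.

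Chance was looked at by other groupings of the samples. The 5 replicate ratios allow 16 sign patterns, and the smallest share they can give is 0.0625, so these patterns are too few for a share under 0.05. The real pattern was 1 of 16 to give as many probes for the strain difference (810, highest other 0), for at least 2-fold (147, highest other 0), for P450 sequences (35, highest other 0) and for the dye effect (12, highest other 0). For the lists, 3 of the 16 patterns gave as many (4, highest other 4). Without the pairing, 1 of 100 splits of the 10 extracts into 5 and 5, the real split, gave as many probes (540, highest other 20). Both extracts of a replicate share their arrays, so extracts cannot be exchanged freely and these splits do not exclude chance. The splits drawn that part all 5 pairs numbered 13, the highest other of them gave 0, and like the 16 sign patterns they are too few for a share under 0.05.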

How the results depend on the processing

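The other pairing of the arrays and the fit without replicates 4 and 5 were chosen after the results were seen; the other alternatives were planned. For the 36 named sequences there were 932 values under alternatives. Of these, 821 kept their direction and their side of the threshold, 105 kept their direction but no longer passed and 6 changed direction. The rule asked for the same sign in all 5 replicates. Direction therefore could not change where replicates were only left out or a batch was taken alone. The fit of separate channels with the replicate block repeats the main test, so its values were set beforehand. In every alternative that gave a value, 16 sequences passed. The count of 810 probes ranged from 141 to 978, and it was 540 for separate channels with no replicate block against 810 with the block. Median centring, which moved the median log2 ratio of all tested probes from 0.06 to 0.15, gave 363 probes (245 higher, 118 lower), 15 P450 sequences, 21 named sequences and 631 probes with a dye effect (627 of them higher in Cy5). It turned RPS3_001, RPS3_003 and RPS3_004 to 0.036, 0.095 and 0.079. Only the arrays with Ogasawara in Cy5 gave 0.021, 0.048 and 0.015 for them, and only those with JPal-per in Cy5 gave 490 probes. A normexp offset of 0 gave 233 probes with at least 2-fold and 258 with a dye effect, the processed signals 392 and 21, and the ratios deposited by the authors 392 and 22. The dye effect reached 120 probes with the strict filter, 183 with trend and robust and 0 unmoderated. Within the batch of replicates 2 and 3 there were 362 probes and 23 P450 sequences. Without replicates 4 and 5 there were 141 probes (66 higher, 75 lower), 89 with at least 2-fold, 9 P450 sequences and 19 named sequences, with fewer replicates as part of that alternative. Leaving out 1 replicate gave 499 to 949 probes, 128 to 156 with at least 2-fold, 28 to 44 P450 sequences, 4 lists each time, 30 to 36 named sequences and 0 to 228 probes with a dye effect. With the strict filter the redox partners, the target sites and the codes A304 to A315 had too few members for the set test. The lists past the threshold numbered 3 to 6 over all alternatives. The causes of these changes were not tested. The 141 probes without replicates 4 and 5 were fewer than the 362 and 723 within the 2 batches, which held fewer replicates still. Signal over background, with a Cy5 median down to 1.25, limits dim probes.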

Other observations

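The similarity of P450 sequences against their ratios, and the run P450_030 to P450_037, were tested with predictions written before those values were computed, but the latter pattern had been seen in the ratios; the other pairing of the arrays was chosen after the results were seen. Several other transcripts differed between the strains; these were picked after their values were seen. Opsins are the light receptors of the eye, and the sequences AY297442_054 and AY749413_120 both carry an opsin segment. They lay at -0.50 ± 0.33 and -0.51 ± 0.34 (SD, n = 5, adjusted p = 0.02 and adjusted p = 0.0213), with the same sign in 4 of 5 replicates, and share 9 near-identical probes; the brightest probe of AY749413_120 was saturated on 1 array in each strain. AF271695_017, which carries a segment of trypsin-like serine proteases, lay at 0.44 ± 0.23 (SD, n = 5, adjusted p = 0.0122), on a probe saturated on 2 arrays in JPal-per and 1 in Ogasawara. Its dye effect of -0.63 (limma adjusted p = 0.0696) was larger in size than that ratio. The mean ratio of AF271695_017 thus changed direction between the orientations of the dyes. AY189807_047 was higher at 0.82 ± 0.18 (SD, n = 5, adjusted p = 7.63e-04), with the same sign in 5 of 5 replicates.

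A hypothesis was that P450 sequences P450_030 to P450_037 belong to a shared subfamily. Of these 8 sequences, 7 were lower and 1, P450_032, was higher, and they held both extremes of the P450 sequences, -3.52 and 4.58. The other 53 sequences with the P450 code had 12 lower, 13 higher and 28 not past the threshold. The aligned probes of the 8 sequences shared 35.7 bases on average, against 25.4 over all pairs of P450 sequences (one-sided permutation p = 1.0e-05, the smallest these permutations can give), which is consistent with a shared subfamily. Whether a shared subfamily bears on the ratios was not tested by this.

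A second hypothesis was that P450 sequences with more bases in common have more similar ratios. Over 1763 pairs of 61 P450 sequences, without the 2 pairs that share at least 50 bases on average and those with fewer than 3 aligned probes, the Spearman correlation between shared bases and the difference in ratio was 0.0599 (two-sided permutation p = 0.446). The correlation lay above the bound of the prediction, so the hypothesis did not hold for these pairs; sequences are not independent replicates.

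Replicate ratios correlated across genes with r from 0.67 (replicates 1 and 2) to 0.93. Once the mean of its orientation was taken from each array, the arrays of the same number correlated with r = 0.75, 0.77, 0.46, -0.20 and 0.17 for replicates 1 to 5 across genes, which are not independent replicates. For the crossed arrays of replicates 4 and 5 the values were 0.54 and 0.33, and other arrays of opposite orientation that share no extract by the labels reached up to 0.41. With those arrays paired the other way, 741 probes passed, 147 of them with at least 2-fold. Whether the second arrays of replicates 4 and 5 were exchanged in the labels stays open, and it bears on the SD of the named sequences.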
